A study of Mus musculus with 6 samples.

How the data were processed

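Retinal RNA of mice was compared on 6 Agilent whole mouse genome arrays (design 026655) with 60-base probes. RNA was extracted with Trizol from 4 pooled retinas, reverse transcribed and labelled directly with Cy3 or Cy5 dCTP, per the labels' protocols, with the control in Cy3 and the treated pool in Cy5 on every array. Whether the control RNA of the arrays came from 1 pool or several is not given in the sources used here. The deposited scanner files hold spot intensity values in 2 channels, as mean and background signals and as processed signals, with log10 ratios; per the file headers they were made with Agilent Feature Extraction 10.7.3.1 (protocol GE2_107_Sep09), while the submitters' processing notes name version 9.3.2.1. The authors also deposited a file of log2 ratio values. Set against each array's log10 ratio, its columns had r between 0.983 and 1.00 and a slope of 3.32, which is the step from log10 to log2, so that they run as Cy5 over Cy3; their medians lay between -0.075 and 0.039, and which centring the authors applied beyond that stays unknown.

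From the mean signal and the median local background, intensities were corrected with normexp (offset 50) and normalized within each array by loess, with 1377 control spots at weight 0, in limma 3.58.1 under R 4.3.3, with version 1.17.8 of data.table. Spots marked as outliers were left out (185 to 274 per array), and spots of a probe were averaged. Of 39429 probes, 26055 were matched to a current mouse gene symbol by accession, 3195 by symbol and 930 by synonym in the table of RefSeq genes, and 9249 kept the name in the file. Probes had to stand well above background in a channel on at least 3 of 6 arrays, which left out 6939. For each gene the probe of highest mean intensity was used, which left 26134 genes or names, 19489 of them matched to a symbol. Among the genes named, 33 had several probes; the probes of 9 differed in sign at PTC and of 7 at 10PTC, 5 of them at each dose with the used probe or another called the opposite way. Srebf2, Vegfa, Kdr, Ccne1, Nr4a2 and Dnaja1 were such genes. No reference genome was used; probe coordinates are those of the array design, built on mm9. Signal over background, not counts, sets the precision: median Cy3 signals were 153 to 221 and median Cy5 signals 187 to 347, before subtraction, against a median background of 26 to 29 and 47 to 48.

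A limma model over the 6 arrays had a coefficient for each dose and none else, with 4 residual and 3.41 prior degrees of freedom. Each dose was tested against 0, the doses against each other, and their mean against 0, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Before the data were examined, 47 gene lists (794 names, of which 765 were measured) of retinal and neighbouring cell types, stress, immune and metabolic pathways were fixed and were tested with camera, ranked, at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists of a comparison. Counts of genes per list are given over all genes and adjusted over the list alone. The genes named were also fixed by rule: per comparison the 6 most increased and 6 most decreased genes that passed, had the same sign on all arrays of the dose and stood above background on all arrays; up to 4 members with the smallest p of each list called; and a panel of 24 genes, of which Icam1 and Hbb-b1 were not measured. Where none passed, the 3 genes of smallest p per direction are named. Genes named outside the rule are said to be so. Some genes that meet the rule are not reported here.

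The steps were tested on simulated data with the real genes' moderated spreads, normal noise and 200 changed genes. For PTC against PBS, 56% of genes changed by 1.25-fold, 96% at 1.5-fold and 100% at 2-fold were recovered among 26128 genes, with 11 false calls; for 10PTC against PTC it was 16%, 84% and 100%, with 13 false calls. A list shifted by 0.25 log2 units was called for PTC (camera adjusted p = 6.2e-06) and no other list was. The noise was drawn independently for each gene. The simulation therefore cannot show how often camera calls lists of genes that vary together.

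Alternatives fixed at the same time were the scanner software's processed signals, no background subtraction, an offset of 0, median centring, Aquantile and scale normalization, 2 other filters, outlier spots kept, other rules for probes of a gene, the authors' table, each dose fitted alone, array quality weights, replicate number or slide as a block, values within each slide, trended and robust moderation, each array left out in turn, and 2-fold changes without a test but with the same sign on every array (between the doses, groups that do not overlap). A correction for base composition of the probes, a treat test against 1.5-fold and the Cy5 channel alone were added after seeing the data.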

Results

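Gene expression was measured in the retina of male C57BL/6 mice aged 8 weeks, 7 days after an injection into the vitreous, the gel that fills the eye, of phosphate-buffered saline (PBS) or of titanium dioxide nanoparticles. The nanoparticles were given at a dose that the labels call PTC and at 10 times that dose, called 10PTC. Each group had 12 mice, and 4 retinas were pooled per tube, which gave 3 pools per dose. The 6 arrays were of the 2-colour kind, with a treated pool in Cy5 and PBS control RNA in Cy3 on each, and no array had the dyes the other way round. Of the 43020 gene probe spots per array, 67.2% to 84.0% stood well above background in a channel, and no spot was saturated. Expression is given as log2 of treated over control, so that 1 is a doubling. Limma p-values measure the spread among pools of 4 retinas, and the number of arrays limits their precision. That spread is moderated and taken over both doses together. The p-values therefore do not rest on the SD given for a single dose.

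The control channel varied less than pools of separate animals in the treated channel did. Between 2 arrays of a slide the Cy3 signals differed with a median spread of 0.057 log2 units and at most 0.093, against a median of 0.15 and at least 0.11 for Cy5. Between arrays of different slides the spread was larger, with a median of 0.22 for Cy3 and 0.30 for Cy5. Whether both slides carried the same control RNA therefore cannot be told. The ratios are compared with 0, as against 1 control RNA, and this leaves out the spread of the control itself. Any effect of the dyes on a gene is part of its ratio and cannot be told from treatment in the comparisons with PBS. Slide 1 held PTC replicates 1 and 2, and slide 2 held PTC replicate 3 and all 3 10PTC arrays.

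The comparison of PTC with PBS asked which retinal transcripts differed after the lower dose. Most genes listed for glial reaction, microglia and interferon rose, and most listed for skeletal muscle, red blood cells, cholesterol synthesis and ganglion cells fell. Of 26134 genes tested, 8656 passed an adjusted p of 0.05 in limma, 4404 higher and 4252 lower. Most changes were small. They had a median size of 0.28 log2 units among the genes that passed. Of these, 122 genes rose and 83 fell by 2-fold or more. The 6 largest increases among those allowed by the naming rule were in Ecel1 (2.81 ± 0.89, SD, n = 3), an endopeptidase of neurons, Lyz1 (2.67 ± 1.18), a lysozyme, Bcl3 (2.59 ± 1.13), a regulator of NF-kappa-B, Serpina3n (2.45 ± 1.04), a protease inhibitor of reactive glia, Timp1 (2.20 ± 1.16), an inhibitor of metalloproteinases, and Edn2 (2.13 ± 0.73), an endothelin. Their limma adjusted p-values lay between 0.00129 and 0.00540. The 6 largest decreases were in Myl1 (-3.71 ± 1.48, SD, n = 3), Cfd (-3.64 ± 0.82), Cox6a2 (-3.49 ± 0.65), Sln (-3.34 ± 0.73), Tnni2 (-3.22 ± 0.68) and Myh1 (-3.11 ± 0.98). All but Cfd, a serine protease abundant in fat, encode proteins of striated muscle. In the coordinates of the array design (mm9), the Ecel1 probe lies on chromosome 1 at 89044233 to 89044292, the Bcl3 probe on chromosome 7 at 20393826 to 20393885, the Myl1 probe on chromosome 1 at 66970948 to 66971007 and the Cfd probe on chromosome 10 at 79355302 to 79355361. Whether these 60-base probes lie in a coding exon or a UTR is not given in the sources used here.

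The list of retinal gliosis and injury genes had 20 measured members, of which 18 rose and none fell at PTC, with a median of 1.40; adjusted over the list alone, 18 rose as well. Besides Bcl3, Edn2 and Serpina3n, the complement gene C4b rose by 1.56 ± 0.30 (SD, n = 3), the transcription factor gene Cebpd by 2.03 ± 0.76, Chil1 by 2.00 ± 0.78, Lcn2, which encodes an iron-binding protein of inflammation, by 1.69 ± 0.97, and Gfap, the intermediate filament of reactive astrocytes and Muller glia, by 1.61 ± 0.62. The 3 Gfap probes ranged from 0.10 to 1.80. Glul, the glutamine synthetase of Muller glia, fell to -0.64 ± 0.21. Of 20 microglia and macrophage genes 17 rose and none fell, with a median of 1.11, and 17 rose adjusted over the list alone. Examples are the protease gene Ctss (1.94 ± 0.59), Lyz2 (1.92 ± 0.80), Trem2 (1.91 ± 0.80), the fractalkine receptor gene Cx3cr1 (1.34 ± 0.47) and Aif1 (1.24 ± 0.52). Markers of the vascular endothelium, another cell type of the retina, had a median of -0.01, with 3 of 15 higher and 3 lower. Camera called the gliosis list (adjusted p = 4.9e-08) and the microglia list (adjusted p = 4.66e-08) with its preset correlation, and neither with an estimated correlation (adjusted p = 0.806 for both). PTC replicate 1 had the highest median of both lists, 1.89 and 1.68, and PTC replicate 2 the lowest, 0.79 and 0.59. In the same pools the skeletal muscle list lay at -2.86.

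Interferon-stimulated genes had a median of 0.76 at PTC, and 15 of 20 rose, 19 adjusted over the list alone. Ifit1 rose by 1.51 ± 0.88 (SD, n = 3) and Irf9 by 0.81 ± 0.51. Of 18 antigen presentation genes 11 rose, 14 adjusted over the list alone, with a median of 0.75. B2m, the light chain of MHC class I, rose by 1.18 ± 0.64 and the class II gene H2-Eb1 by 0.84 ± 0.49. Of 17 complement genes 10 rose and 1 fell, 11 and 1 adjusted over the list alone, with a median of 0.51. C1qa rose by 1.48 ± 0.62 and C1qb by 1.38 ± 0.58. Of 16 cytokine and chemokine genes 12 rose, 13 adjusted over the list alone, with a median of 0.38. The chemokine gene Ccl12 rose by 1.12 ± 0.34, and Ccl3, whose Cy3 signal was not well above background, was at least 1.70-fold higher. Such bounds set the Cy5 mean against the lowest Cy3 signal well above background and are open to dye bias. Of 22 lysosomal and uptake genes 13 rose and 1 fell, 14 and 1 adjusted over the list alone, with a median of 0.35. Lamp2 rose by 0.75 ± 0.33 and the channel gene Mcoln1 fell to -0.38 ± 0.06. Of 12 necroptosis and pyroptosis genes 6 rose, also adjusted over the list alone, among them Ripk1 (0.41 ± 0.12) and Casp1 (0.81 ± 0.50), with a list median of 0.27. Camera called these 6 lists at adjusted p between 1.95e-06 and 0.0116, and none with an estimated correlation (adjusted p = 0.806 for each). PTC replicate 1 stood apart, with medians of 1.42 for the interferon, 1.28 for the antigen presentation and 0.81 for the complement list, against 0.17 to 0.53 for these lists in the other PTC replicates. Without it these medians were 0.42, 0.41 and 0.24, and the lists stayed called. The cytokine, lysosomal and necroptosis medians were also highest in PTC replicate 1, at 0.59, 0.63 and 0.54. In the other PTC replicates they lay between 0.055 and 0.33. The necroptosis list was not called after median centring (adjusted p = 0.208), on probes well above background in both channels on all arrays, or without PTC replicate 1.

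Ganglion cell markers mostly fell at PTC. In the bipolar, amacrine and synaptic lists some genes fell and others did not pass, while 2 synaptic genes rose. Of 15 retinal ganglion cell genes 11 fell and 1 rose, 12 and 1 adjusted over the list alone, with a median of -0.47. The transcription factor gene Pou4f1 lay at -0.72 ± 0.36 (SD, n = 3), the RNA-binding protein gene Rbpms at -0.44 ± 0.14 and the tubulin gene Tubb3 at -0.52 ± 0.11. Of 15 bipolar cell genes 8 fell, with a median of -0.29, among them Vsx1 (-0.72 ± 0.22) and Pcp2 (-0.74 ± 0.31); adjusted over the list alone, 8 fell and 1 rose. Of 14 amacrine cell genes 7 fell, 9 adjusted over the list alone, with a median of -0.26, among them the acetylcholine transporter gene Slc18a3 (-0.60 ± 0.18) and Chat (-0.39 ± 0.27). Of 22 synaptic genes 11 fell and 2 rose, also adjusted over the list alone, with a median of -0.20. Syp lay at -0.37 ± 0.06 and the GABA receptor gene Gabrr1 at -0.58 ± 0.35. The camera adjusted p was 0.000233 for the ganglion cell list and between 0.000875 and 0.00657 for the other 3. With an estimated correlation no list passed (adjusted p = 0.806, and 0.815 for the synaptic list). After median centring of the arrays in place of loess, the bipolar, amacrine and synaptic medians were -0.13, -0.06 and -0.06 and none was called (adjusted p 0.150, 0.0831 and 0.156). The ganglion cell list stayed called. PTC replicate 1 stood apart, with medians of -0.70 for ganglion cells, -0.54 for bipolar cells, -0.48 for amacrine cells and -0.37 for synaptic genes. In replicates 2 and 3 they were -0.32 and -0.40, -0.10 and -0.15, -0.10 and -0.20, and -0.10 and -0.15. The synaptic list was not called without this array. The rod median was -0.26 there, against 0.31 and 0.07. Rod photoreceptor genes had a median of 0.01, with 5 of 18 higher and 2 lower, and cone genes a median of -0.04, with 2 of 13 higher and 3 lower; neither list was called. The blue cone opsin gene Opn1sw fell to -0.46 ± 0.08 (SD, n = 3).

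All 14 skeletal muscle genes fell at PTC, also adjusted over the list alone, with a median of -2.86 (camera adjusted p = 4.66e-08; adjusted p = 0.806 with an estimated correlation). Fry, which tests whether the genes of a list move one way without comparing them with other genes, called this list (adjusted p = 0.00350) and no other. Ckm, the muscle creatine kinase, lay at -2.14 ± 0.15 (SD, n = 3), the actin gene Acta1 at -2.36 ± 0.18 and the myoglobin gene Mb at -2.89 ± 0.33. Of 6 measured red blood cell genes 5 fell, also adjusted over the list alone, with a median of -0.72, among them the globin gene Hba-a1 (-1.41 ± 0.78) and Alas2 (-1.41 ± 0.56), the first enzyme of heme synthesis in erythroid cells. The median was -0.26 without a filter on dim probes. Of 17 cholesterol synthesis genes 13 fell, 14 adjusted over the list alone, with a median of -0.42. Dhcr7 lay at -0.42 ± 0.09 and Mvk at -0.38 ± 0.07. Srebf2, which controls the pathway, lay at -0.53 ± 0.06 on its brighter probe and at 0.49 on its other probe. Among lists with fewer members moving, 6 of 15 pigment epithelium and pigment cell genes rose, also adjusted over the list alone (median 0.29; Lrat 0.67 ± 0.21, Tyrp1 0.84 ± 0.30), 9 of 20 Nrf2 target genes rose and 1 fell, 11 and 1 adjusted over the list alone (median 0.25; Me1 0.37 ± 0.04), and 4 of 17 cell cycle genes rose and 1 fell, 5 and 1 adjusted over the list alone (median 0.21; Mcm3 0.63 ± 0.35). Camera called the red blood cell list at adjusted p = 0.0127 and the other 4 at adjusted p between 1.17e-05 and 0.00506, and none with an estimated correlation (adjusted p = 0.806 for each). Without PTC replicate 1 the Nrf2 and cell cycle lists were not called (adjusted p = 0.0747 and 0.0934).

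In all, camera called 18 of 47 lists for PTC, 11 higher and 7 lower, and fry 1. With the slide as a block 5898 genes and 20 lists were called. Within slide 1, which held the other 2 PTC arrays and no 10PTC array, 289 genes and 18 lists were called, with medians of 1.49 for gliosis, 1.08 for microglia and -2.34 for muscle. Within slide 2, where the single PTC array is assumed to vary like the 10PTC arrays, it was 1715 genes and 22 lists, with medians of 1.21, 1.12 and -3.40. Without PTC replicate 3, 5004 genes were called, and a limma treat test against 1.5-fold, chosen after seeing the data, called 12 higher and 46 lower. Median centring moved the split from 4404 higher and 4252 lower to 8203 higher and 4212 lower.

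**Figure D1:**
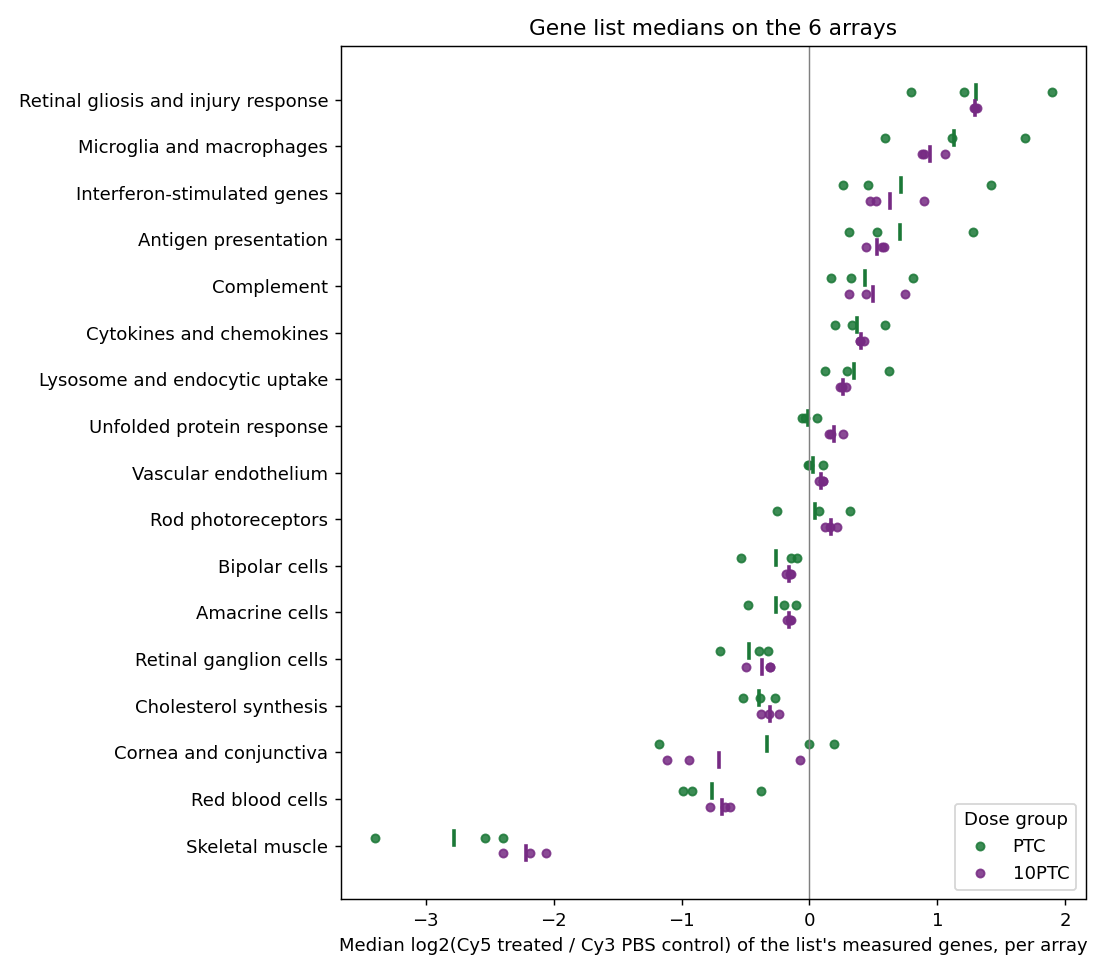
Median log2 ratio of treated over PBS control over the measured genes of 17 gene lists; each point is 1 array (3 per dose) and each vertical bar the mean of a dose. The skeletal muscle medians lie between -3.40 and -2.06 and the gliosis medians between 0.79 and 1.89, while the amacrine medians, below 0 here, turn above 0 at 10PTC after median centring.

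The comparison of 10PTC with PBS asked the same of the higher dose. Most gliosis, microglia, interferon, complement and cytokine genes were again higher and most muscle, cholesterol synthesis and ganglion cell genes again lower. Some genes of the unfolded protein response (9 of 18) and the heat shock response (6 of 14) were higher, and neither list passed with an estimated correlation (adjusted p = 0.842). Of the 26134 genes 7231 passed, 3762 higher and 3469 lower, with a median size of 0.27 among them; 92 rose and 77 fell by 2-fold or more. The largest increases were in Bcl3 (2.84 ± 0.13, SD, n = 3), Ecel1 (2.82 ± 0.39), Cebpd (2.63 ± 0.24), the serine protease gene Prss56 (2.49 ± 0.45), Edn2 (2.38 ± 0.08) and Lyz1 (2.20 ± 0.07), with limma adjusted p between 0.000478 and 0.00644. The largest decreases were in Cfd (-3.77 ± 0.11, SD, n = 3), Cox6a2 (-2.98 ± 0.30), Myl1 (-2.76 ± 0.42), Ckmt2 (-2.73 ± 0.17), Tnni2 (-2.71 ± 0.11) and Pi16 (-2.58 ± 0.93). The Prss56 probe lies on chromosome 1 from 89083595 to 89083751 (mm9), close to that of Ecel1.

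At 10PTC 17 of 20 gliosis genes rose, with a median of 1.30, and 16 of 20 microglia genes, with a median of 0.97; none of either fell, and the counts were the same adjusted over the list alone. Gfap rose by 1.44 ± 0.12 (SD, n = 3), Lcn2 by 1.96 ± 0.48, the ferroxidase gene Cp by 1.67 ± 0.23, Ctss by 1.68 ± 0.17 and Aif1 by 1.08 ± 0.17. The 3 Gfap probes ranged from 0.25 to 1.83 and the 2 Cp probes from 0.65 to 1.67. Glul lay at -0.61 ± 0.08. The endothelial list had a median of 0.10, with 2 of 15 genes higher and 1 lower, and the muscle list lay at -2.22 in the same pools. Of 20 interferon-stimulated genes 11 rose, 16 adjusted over the list alone (median 0.67; Irf9 0.92 ± 0.12), of 18 antigen presentation genes 9, and 10 adjusted over the list alone (median 0.61; H2-D1 1.05 ± 0.08), and of 16 cytokine genes 10, and 11 adjusted over the list alone (median 0.40; the chemokine gene Cxcl10 1.78 ± 0.34). Of 17 complement genes 9 rose and 1 fell, 12 and 1 adjusted over the list alone (median 0.53; Cfi 1.03 ± 0.23). Of 22 lysosomal genes 8 rose and 1 fell, 11 and 1 adjusted over the list alone (median 0.27). Camera called these 7 lists at adjusted p between 7.55e-08 and 0.00282, and none with an estimated correlation (adjusted p = 0.842 for each).

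Of 18 genes of the unfolded protein response, which answers misfolded protein in the endoplasmic reticulum, 9 rose and 2 fell at 10PTC, also adjusted over the list alone, with a median of 0.20. The transcription factor genes Atf3 (1.31 ± 0.13, SD, n = 3) and Atf4 (0.44 ± 0.10) and the chaperone genes Hspa5 (0.29 ± 0.03) and Hsp90b1 (0.26 ± 0.04) were among them, though Hspa5 was not called in 10 of 25 alternatives (adjusted p up to 0.262). Of 14 heat shock genes 6 rose, also adjusted over the list alone, with a median of 0.20, among them Hspa8 (0.46 ± 0.07) and Hspd1 (0.24 ± 0.02). Both lists were called by camera (adjusted p = 0.0144 and 0.0270), neither with an estimated correlation, and fry called the heat shock list (adjusted p = 0.0285). The heat shock call ended with the slide as a block (adjusted p = 0.0932), and the unfolded protein response call without 10PTC replicate 2 (adjusted p = 0.0682).

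All 14 muscle genes fell at 10PTC, also adjusted over the list alone, with a median of -2.22 (fry adjusted p = 0.00755), among them Ckm (-1.80 ± 0.12, SD, n = 3) and Acta1 (-2.08 ± 0.18). Of 17 cholesterol synthesis genes 11 fell, 13 adjusted over the list alone (median -0.30; Insig1 -0.74 ± 0.26, Hmgcs1 -0.49 ± 0.08), and of 15 ganglion cell genes 10 fell and 1 rose, 11 and 1 adjusted over the list alone (median -0.36; Isl2 -0.63 ± 0.07). Bipolar (5 of 15 lower; median -0.18) and amacrine genes (4 of 14 lower; median -0.13, but 0.089 after median centring) had the same counts adjusted over the list alone. Of 6 red blood cell genes 3 fell, also adjusted over the list alone, with a median of -0.67, or -0.20 without a filter on dim probes. After median centring the cholesterol synthesis and ganglion cell lists stayed called, with medians of -0.085 and -0.18. Of 11 cornea and conjunctiva genes, markers of surface tissue of the eye, 3 fell and 1 rose, 4 and 1 adjusted over the list alone, with a median of -0.74. The keratin genes Krt14 (-0.74 ± 0.50) and Krt4 (-0.48 ± 0.28) fell and Sprr1a rose by 1.29 ± 0.37; they were not called in 7, 7 and 10 of 25 alternatives. The camera adjusted p of these 7 lists lay between 7.55e-08 and 0.0325, and no list passed with an estimated correlation (adjusted p = 0.842 for each). Median centring ended the bipolar (adjusted p = 0.645), amacrine (0.804) and red blood cell (0.171) calls. With the slide as a block neither the cornea list (adjusted p = 0.832) nor the red blood cell list (adjusted p = 0.0667) was called. The cornea list was also not called without 10PTC replicate 1 or on probes well above background in both channels. The bipolar list was not called without 10PTC replicate 2, and the amacrine list not on processed signals or without 10PTC replicate 2 or 3. The red blood cell list was not called on processed signals, on the authors' table, without 10PTC replicate 2 or after the base composition correction, which was chosen after seeing the data.

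Of the fixed panel of 24 genes, 22 were measured. The metallothionein genes Mt1 (0.79 ± 0.36 at PTC and 0.52 ± 0.08 at 10PTC, SD, n = 3) and Mt2 (0.98 ± 0.53 and 0.65 ± 0.10), the cell cycle inhibitor gene Cdkn1a (0.54 ± 0.54 and 0.60 ± 0.06) and the macrophage gene Cd68 (0.50 ± 0.31 at PTC, and at least 1.48-fold at 10PTC, where Cy3 was not well above background) passed at both doses. Il1b was at least 1.21-fold higher at PTC and 1.23-fold at 10PTC, but its mean log2 ratio at 10PTC was -0.019 after median centring, and it was not called in 8 of 25 alternatives at PTC and 10 of 24 at 10PTC. Cdkn1a was not called in 13 of 26 alternatives at PTC and 10 of 25 at 10PTC, and its other probe lay at 0.13 and 0.04. The lens crystallin gene Cryaa passed at PTC alone (0.68 ± 0.59 and 0.62 ± 0.40), and the growth factor gene Vegfa at 10PTC alone (0.11 ± 0.13 and 0.21 ± 0.11; its other probe lay at -0.14 and -0.20), with no detectable difference between the doses for either (limma adjusted p = 0.972 and 0.763). The median of the lens list ranged from -0.51 to 0.67 over the PTC arrays and from -0.075 to 0.68 over the 10PTC arrays. Cryaa at PTC was not called in 13 of 26 alternatives, Vegfa at 10PTC in 9 of 25, and Nqo1 at 10PTC in 10 of 25. Nqo1 (0.02 ± 0.18 and -0.24 ± 0.04) and Rpe65 (0.09 ± 0.09 and -0.32 ± 0.12) fell at 10PTC. The heat shock gene Hspa1a fell at PTC (-0.27 ± 0.06) and did not pass at 10PTC (0.08 ± 0.19). Hspa1a at PTC was not called in 8 of 26 alternatives, and Mt1 and Mt2 at 10PTC in 6 and 7 of 25. Tnf, Kdr, Cdh5 and Hmox1 passed at neither dose on the probes used, while another Kdr probe passed in the opposite direction at both (-0.36 and -0.50). Hmox1, the heme oxygenase of oxidative stress, ranged from -1.88 to 0.99 over the 6 arrays.

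**Figure D2:**
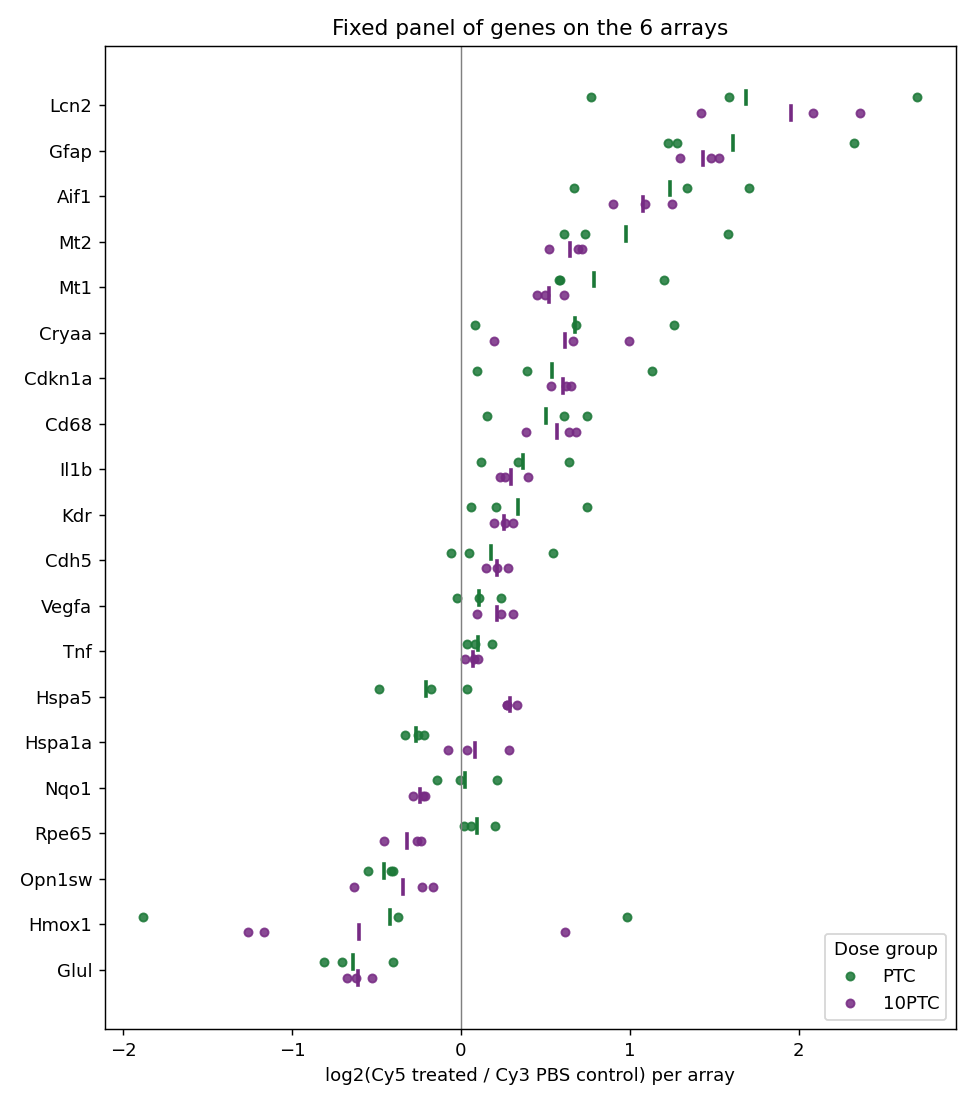
Log2 ratio of treated over PBS control for genes of the fixed panel; each point is 1 array (3 per dose) and each vertical bar the mean of a dose. On the probes used, Gfap lies above 1 on all 6 arrays (1.23 to 2.33), Glul below 0 (-0.81 to -0.40), and Hmox1 spreads from -1.88 to 0.99. Il1b, above 0 here, has a mean of -0.019 at 10PTC after median centring.

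In all, camera called 16 lists at 10PTC, 9 higher and 7 lower, and fry 2. Within slide 2, which holds all 10PTC arrays, 9369 genes and 19 lists were called, and the gliosis, microglia and muscle medians were the values above. With the slide as a block, which sets 10PTC at the mean of both slides from PTC arrays alone, 1009 genes and 14 lists were called, with medians of 1.38, 0.93 and -1.54. The number of genes also fell to 1360 without 10PTC replicate 1 and to 1566 without 10PTC replicate 3. It was 4440 on the scanner software's processed signals, 4579 on the authors' value table, 12261 with array quality weights, and 43 (8 higher, 35 lower) by treat against 1.5-fold, chosen after seeing the data. Median centring gave 14634, and moved the split from 3762 higher and 3469 lower to 9646 higher and 4988 lower.

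Over both doses, the mean against PBS passed for 12461 genes, 6331 higher and 6130 lower. Camera called 18 lists, none with an estimated correlation, and fry 15. With the slide as a block 10368 genes and 18 lists were called, and within slide 2 9122 genes and 21 lists. Median centring gave 11044 higher and 6503 lower, and treat against 1.5-fold 125 genes. The mean log2 ratios of the doses correlated across genes, which are not independent replicates, with Pearson's r = 0.868 and Spearman's rho = 0.805. Unchanged groups simulated against 1 common control gave r = 0.751, and against controls shared by replicate number r = 0.502. The observed covariance was 0.0595, against 0.0181 and 0.00605 in these simulations. They assumed a control spread equal to the moderated spread of the ratios, and no dye effect. A control or dye effect of another size is therefore not excluded as the source of the difference. The r was 0.838 with the slide as a block and 0.845 within slide 2. Of the genes that rose, 2775 did so at both doses (634 for independent lists), and of those that fell, 2410 did (564 for independent lists); at 2-fold or more it was 74 and 70 genes. Since the control channel could not be split, the part of this overlap that is due to the shared control RNA and dyes is unknown.

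**Figure D3:**
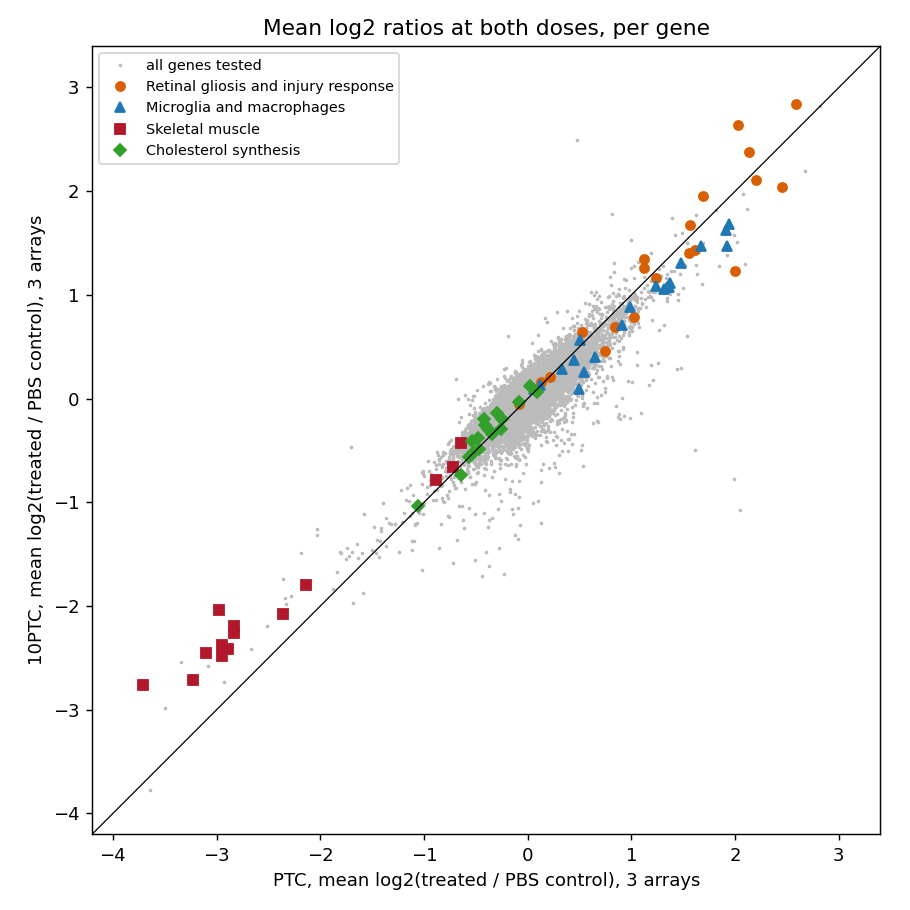
Mean log2 ratio of treated over PBS control at PTC (horizontal axis) and 10PTC (vertical axis), 3 arrays each; each grey point is 1 of 26134 genes, coloured symbols are members of 4 gene lists, and the line marks equal ratios. Genes lie along the line (r = 0.868), with gliosis and microglia genes at the upper end and muscle genes at the lower end.

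The comparison of 10PTC with PTC asked whether the effect depended on dose, and a dye effect common to all arrays cancels in it. No gene passed in limma; the smallest adjusted p was 0.228, 2130 genes had an unadjusted p under 0.05, and 0 genes passed with the slide as a block or within slide 2. In simulated data with the same spread, 84% of 50 genes that differed by 1.5-fold between the doses were called. All of 50 that differed by 2-fold were called too. That simulation had independent normal noise, 200 changed genes and no slide effect, so it does not exclude 2-fold differences here. Prss56, 2.02 log2 units apart, did not pass. The groups did not overlap for 4053 genes, 15.5% of those tested, where chance gives 10%. That share takes no account of the slides, and with the slide as a block 881 genes, in place of 2130, had an unadjusted p under 0.05. Prss56 had the largest difference of the genes with the smallest p (2.02, SE 0.22), at 0.47 ± 0.23 for PTC and 2.49 ± 0.45 for 10PTC (SD, n = 3). The other genes named under the rule, none passing, were Peli3 (0.64), Adamts19 (0.55), Ccn4 (-0.66), BC065403 (-0.78) and Gm3448 (-0.50), with limma adjusted p from 0.228 to 0.288. On the Cy5 channel alone, chosen after seeing the data, BC065403 and Ccn4 were called (limma adjusted p = 0.0388 and 0.0402), also lower at 10PTC. The other 18 genes called there were higher at 10PTC, some with ratios that ran the other way, such as 1700022A21Rik (2.13 on Cy5, -0.47 as ratio within slide 2). Cy5 alone keeps any difference between the slides, which nearly follows dose. Among 5 genes with groups that did not overlap and lay 2-fold or more apart, chosen after their values were seen, were Prss56 and, lower at 10PTC, Col1a1 (-1.14), Aldh3a1 (-1.01), Ly6g6c (-1.10) and Rbpjl (-1.05). Within slide 2 the difference was 2.12 for Prss56, but -0.28, -0.30, -0.11 and -0.07 for the other 4, so that most of their difference came from the PTC arrays of slide 1. Without PTC replicate 3, 1 gene passed, Slurp1 (-4.19, adjusted p = 0.0465), likewise singled out after its values were seen. Dose then equals slide, and PTC replicate 3 had Slurp1 at -0.87, within the range of the 10PTC arrays.

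For lists, the evidence of a difference between the doses was weak: 8 of 10 splits of the arrays, the real one among them, gave at least 11 called lists, the real number, and no member passed over all genes. The unfolded protein response list was higher at 10PTC, with a median difference of 0.12, 4 of 18 genes higher adjusted over the list alone, and differences of 0.52 for Xbp1, 0.42 for Calr, 0.37 for Creld2 and 0.50 for Hspa5. The heat shock list had a median of 0.14, with 3 of 14 genes higher adjusted over the list alone and a difference of 0.35 for Hspa8, and the immediate early gene list a median of 0.14, with 2 of 21 higher adjusted over the list alone and 0.53 for Npas4. Muscle genes lay nearer to the control at 10PTC (0.49), as did amacrine (0.11) and synaptic genes (0.08). Over the arrays of slide 2 the muscle genes had a median range of 1.12 log2 units in Cy5 and 0.080 in Cy3. On slide 1 it was 0.19 and 0.037. The slide 2 range spans PTC replicate 3 and all 10PTC arrays. It therefore cannot tell dose from muscle RNA that varied between treated pools. Lower at 10PTC were the lists of matrix genes (-0.28; Lum -0.80), pigment epithelium genes (-0.21; 1 of 15 lower adjusted over the list alone; Rpe65 -0.41), microglia (-0.22; Csf1r -0.24), Nrf2 targets (-0.16; Nqo1 -0.26) and ribosomal proteins (-0.07; Rpl4 -0.16). In the muscle, amacrine, synaptic, matrix, microglia, Nrf2 and ribosomal lists no gene passed adjusted over the list alone. Camera called these 11 lists at adjusted p between 0.000135 and 0.0236; with an estimated correlation each had adjusted p = 0.891, and fry called none, with adjusted p of 0.451 for the unfolded protein response and 0.364 for heat shock.

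With the slide as a block 10 lists were called between the doses and within slide 2 13, but the matrix (-0.02, adjusted p = 0.606), amacrine (0.02, adjusted p = 0.908), synaptic (0.06, adjusted p = 0.235) and Nrf2 (-0.10, adjusted p = 0.0750) lists were not called with the block, nor within slide 2, and the heat shock list was not called with the block (0.15, adjusted p = 0.0763). The unfolded protein response (0.18), immediate early (0.21), muscle (0.97), ribosomal (-0.13), microglia (-0.19) and pigment epithelium (-0.11) lists were called under both, with the same median, since both estimates rest on slide 2 and there on PTC replicate 3 alone. Over all alternatives the muscle median ranged from 0.15 to 0.97, and this list was not called with scale normalization or with trended and robust moderation; its median in PTC replicate 3 was -3.40, against -2.54 and -2.39 in the others. The microglia list was not called under these 2 settings or without 10PTC replicate 2, and the pigment epithelium list not without 10PTC replicate 1. Without PTC replicate 1 the microglia median was 0.026 and the amacrine median -0.0062, and neither was called, nor were the matrix, Nrf2 and synaptic lists; 19 lists were called then, 26 without PTC replicate 2 and 7 without 10PTC replicate 1. The heat shock list was not called without PTC replicate 2, the matrix, amacrine and synaptic lists not without 10PTC replicate 1, the immediate early list not without PTC replicate 2 or 3, and the ribosomal list not after median centring (-0.0013, adjusted p = 0.605). On the Cy5 channel alone, chosen after seeing the data, 3 lists and 20 genes were called; of the 11 lists, the muscle, matrix and Nrf2 lists kept their call.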

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

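Of the tests in this part, those on PTC replicate 1, on the share of neuronal RNA, on the control RNA and on the 2 slides were chosen only after the result was seen. Groups of 3 arrays were not tested for outliers. For 9 named genes and 1 list all 3 PTC arrays lay on one side of the control and all 3 10PTC arrays on the other. As differences of 10PTC minus PTC, they were Xbp1 (0.52), Calr (0.42), Creld2 (0.37), Hsph1 (0.35), the hypoxia list (median 0.11), Rpe65 (-0.41), Rdh5 (-0.41), Ccn4 (-0.66), BC065403 (-0.78) and Gm3448 (-0.50). The limma test of the difference passed for none of the genes (adjusted p from 0.228 to 0.570), and camera did not call the hypoxia list (adjusted p = 0.0917).

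Skeletal muscle genes lay below the control on all 6 arrays, with list medians from -3.40 to -2.06. A list of 22 further muscle genes, written before their values were looked at, had a median of -0.57 over both doses. Of these genes 20 lay below 0, which leaves muscle RNA in the control RNA as a candidate source. Over both doses 19 passed in limma as lower and 1 as higher. The higher gene, Cacng1 (0.90), ran against this source. None of the 22 genes stands in another list, and 16 were also above background in Cy5 on all arrays. The abundant transcripts were lower as well, Tnnc2 with mean log2 intensities of 14.16 in Cy3 and 11.44 in Cy5, Mb with 12.67 and 10.02, and Acta1 with 10.89 and 8.67. A dye bias that follows the base composition of the probes is argued against, since the median of the 14 genes was -2.55 after that trend was taken out and -2.53 before. Fat RNA in the control stays open, since 12 fat tissue genes had a median of -0.29 with 10 below 0, beside Cfd (-3.64 at PTC), Adipoq (-1.88) and Fabp4 (-1.59), seen before, and a loss of such transcripts with treatment was not tested apart from this.

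Gliosis and microglia genes lay above the control at both doses. The base composition trend is argued against as the cause, since the lower of both list medians was 1.06 after it was taken out. PTC replicate 1 alone is argued against by the lowest median of either list on the other 5 arrays, 0.59. A lower share of neuronal RNA would raise markers of every other cell type alike, and the microglia median exceeded the endothelium median by at least 0.60 on each array. A control RNA that happened to be low in these genes cannot be told apart from treatment, since the Cy3 channel differed by a median of only 0.057 between arrays of a slide, as 1 control RNA per slide would, and a reaction to the particles stays among the open explanations.

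Cornea and conjunctiva genes lay far apart between arrays, with Krt12 at 3.32, 4.22 and -1.42 in the PTC replicates and between -1.65 and -0.08 at 10PTC. Surface tissue of the eye carried into single pools is a candidate explanation: 15 measured genes of stratified epithelium, listed before they were looked at, ranged over the arrays 3.57 times as widely as genes in general, with Cy5 ranges on slide 2 of 1.09 log2 units for the cornea list against 0.12 in Cy3. None of these genes stands in another list, and 13 were above background in Cy5 on all arrays. A difference between the slides stays open: the 11 cornea genes ranged over a median of 1.00 within slide 2, but 0.54 with 1 array left out, and both slide 1 medians (-0.0030 and 0.19) lay above all of slide 2 (-1.18 to -0.078). No biological explanation was tested.

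Other arrangements of the arrays were also counted, by swapping arrays between doses or, against PBS, by turning the sign of arrays; shared dye or control effects have one sign on all arrays and are not tested by this. For genes, the mean of both doses gave 12461 calls. Only 1 of 32 arrangements gave as many, the real one, and the highest of the others gave 1. This argues against noise independent between arrays as the only source. A control or dye effect shared by all arrays would give the same result. For PTC (8656, highest other 0, 1 of 4 as many) and 10PTC (7231, highest other 0, 1 of 4) the arrangements are too few for a share under 0.05, as they are for 10PTC against PTC, where 0 genes were called, all 10 splits gave as many and the highest other gave 62, when PTC replicates 1 and 2, of slide 1, stood with 10PTC replicate 2. For the number of lists, chance cannot be excluded for the mean of both doses: 18 of 32 arrangements gave as many as the real 18, up to 33. For PTC (18, highest other 26, 3 of 4 as many), 10PTC (16, highest other 20, 2 of 4) and 10PTC against PTC (11, highest other 37, 8 of 10) there are too few. The 37 lists, several times the real 11, arose when PTC replicate 1 stood with 10PTC replicates 1 and 2, and what they reflect was not tested.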

How the results depend on the processing

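The base composition correction, the treat test and the Cy5 channel alone were chosen only after the data were seen. Of 1575 values of called lists under the alternatives, 1485 kept direction and call, 85 lost the call and 5 reversed. All of them used camera with its preset correlation. With an estimated correlation camera called 0 lists in every comparison. Fry called 1 for PTC, 2 for 10PTC, 0 for their difference and 15 for their mean. The 6590 values of named genes include genes not called in the main fit, such as all those between the doses. Of these values, 6070 kept direction and stayed called or uncalled, 423 lost the call and 33 gained it. Another 3 reversed and 61 changed sign without being called either time. All 263 gene values stayed the same in this sense with Aquantile normalization, without the filter on dim probes and with all probes taken separately. These settings leave the ratio of the probe used as it is, or nearly so. They therefore hardly test these values, though they count among the 6070. Signal over background limits the dim genes. On probes well above background in both channels 244 values of named genes could be compared, and all kept direction and stayed called or uncalled. This filter leaves the ratios of a probe as they are and removes the dim genes, so it does not test how dim signal affects them.

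PTC against PBS had 8656 genes: 4608 with each dose fitted alone, 289 within slide 1, 1715 within slide 2, 209 by 2-fold without a test, 58 by treat, and 5004 to 7862 with each array left out. 10PTC had 7231: 4440 on processed signals, 14634 with median centring, 4579 on the authors' table, 12261 with array weights, 1009 with the slide as a block, 183 by 2-fold, 43 by treat, and 1360 (without 10PTC replicate 1) to 9121 with an array left out. 10PTC against PTC had 0: 5 by 2-fold, 20 on Cy5 alone, and 0 to 1 with an array left out. The mean of both doses had 12461: 182 by 2-fold, 125 by treat, and 8899 to 12054 with an array left out. A treat threshold lowers a count by construction; for the others the cause was not tested. Each dose fitted alone gives no difference and no mean of the doses, and slide 1 holds no 10PTC array.

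Lists between the doses numbered 11: 19 with median centring, 7 with scale normalization, 3 on Cy5 alone and 7 to 26 with an array left out. With an array left out, lists ranged from 16 to 21 for PTC, 12 to 19 for 10PTC and 16 to 20 for the mean; the correlation of the doses from 0.814 to 0.870 (0.822 to 0.876 under other alternatives); and of 176 called gene results 130 to 172 were kept, 117 with the slide as a block. Reversed were, with median centring, the amacrine list at 10PTC (0.089) and over both doses (0.033), the synaptic list over both doses (0.030), Tfap2a (0.0097) and Il1b (-0.019) at 10PTC; without PTC replicate 1, the amacrine (-0.0062) and microglia (0.026; -0.46 without PTC replicate 2) lists between the doses; and with the mean of its probes, Ccne1 at PTC (0.18). The cause was not tested.

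A pairing by replicate number could not be shown: deviations of same-numbered arrays correlated at -0.27, 0.15 and 0.20, and not every array correlated best with its own number. With 3 arrays per dose the deviations from a dose mean are not independent, and at PTC they include the slides. The check therefore cannot exclude a pairing. With the replicate number as a block, 6451, 4822, 0 and 10676 genes and 18, 19, 12 and 18 lists were called for PTC, 10PTC, their difference and their mean.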

Other observations

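Further genes, chosen after their values were seen, differed from the control. Crym, which encodes a thyroid hormone binding crystallin, was higher by 1.82 at both doses (limma adjusted p = 0.00233 and 0.00313). The fibrillar collagen gene Col3a1 lay at -1.68 at PTC and -1.97 at 10PTC (limma adjusted p = 0.00760 and 0.00594). The matrix gene Dcn passed at 10PTC (-1.44, limma adjusted p = 0.0199) and not at PTC (-0.86, limma adjusted p = 0.0870). At PTC it lay at -2.03 in replicate 3, on slide 2, and at -0.27 in replicates 1 and 2, on slide 1. Of 14 metal handling genes 8 rose and 2 fell at PTC and 6 rose and 2 fell at 10PTC, with medians of 0.32 and 0.21, and camera called the list at neither dose (adjusted p = 0.187 and 0.177). Of 16 p53 target genes 8 rose and 4 fell at PTC and 6 rose and 2 fell at 10PTC, likewise not called (adjusted p = 0.307 and 0.143).

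Single arrays stood apart for some myeloid genes. The scavenger receptor gene Marco lay at 3.66 in PTC replicate 1 and between 0.18 and 0.40 on the other arrays, and S100a8, abundant in neutrophils, at 2.63 in PTC replicate 1 and between -0.18 and 1.11 elsewhere; neither passed at either dose. The neutrophil list was called at neither dose (adjusted p = 0.699 at PTC and 0.645 at 10PTC).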
